A study of Chrysanthemum x morifolium with 2 samples.

How the data were processed

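RNA from chrysanthemum leaves (cultivar Jinba) was sequenced as 2 libraries, 1 titled CK and 1 titled DgWRKY5. The series text speaks of wild-type leaves and of leaves of plants carrying a DgWRKY5 transgene, and of 2 or 3 replicates. Only 1 sample per group was analysed here. The CK title is not explained in the labels. It is read here as the wild type because the series text names no other group, and both libraries are called by their titles throughout. Whether leaves of several plants were pooled in a library is not given in the sources used here. Per the labels' protocols, total RNA was extracted with Trizol and libraries were built with an Illumina TruSeq RNA kit. Bowtie2 2.0.6 and TopHat2 2.0.9 are named in the submitters' processing notes. The assembly, the counting program and any annotation are not given in the sources used here.

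Each deposited file lists 153887 assembled transcript clusters with an estimated count and an FPKM value, as the authors made them, per the file headers. The estimated count is given to 2 decimals and is a whole number for 61.2% of clusters in the CK library and 61.5% in the DgWRKY5 library (tolerance 1e-09), shares that include the clusters at 0. Of the measured clusters defined below, 29.7% are whole in both libraries. Clusters with a non-whole estimate in either library hold 49.3% of all counts, as arises when reads are divided between similar sequences, and levels of such clusters are uncertain. The FPKM values are taken from their name as counts scaled by length and depth. The length implied by count and FPKM, with the column total as depth, had a median of 778 nt in the CK library and 780 nt in the DgWRKY5 library over 22790 clusters above an FPKM of 5 in both. Among measured clusters it ran down to 1.53 nt, shorter than any assembled sequence, so it is not the length of the sequence itself and is used below only to order clusters from short to long, for clusters with an FPKM of at least 0.5 in either library. It was available for 99.2% of the measured clusters.

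The clusters carry names made of a family number and a member number, and the files pair none of them with a gene name. Gene lists fixed before the data were examined (such as WRKY factors, antioxidant enzymes, photosynthesis and abscisic acid signalling) could therefore not be applied, and the transcript of the transgene is not reported here. What a family number stands for is not given in the sources used here. A family is taken here as the set of clusters that share the first number of their name.

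Estimated counts were rounded to whole numbers. The totals were 15980744 counts in the CK library and 16486004 in the DgWRKY5 library, a ratio of 1.03. Library sizes were adjusted with the TMM method of edgeR 4.0.16 in R 4.3.3, with factors of 1.03 for CK and 0.967 for DgWRKY5. For each cluster with at least 20 counts summed over both libraries, called a measured cluster, the ratio of DgWRKY5 to CK was given an exact 95% interval (Clopper-Pearson, on the binomial distribution of the counts given their sum). A cluster was counted as higher or lower when its whole interval lay beyond 2-fold. The reads carry no known molecular identifiers, so these intervals and the limits given for counts of 0 cover counting error only. With 1 library per group there is no estimate of the spread between plants. No p-value is given, and every ratio describes these libraries and has no replicate check. A count of 0 allows up to 3 counts, which is 0.188 CPM (depth-scaled counts) of the unadjusted total in the CK library and 0.182 CPM in the DgWRKY5 library. The fold bounds printed for clusters at 0 come from the exact interval and do not use this limit.

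Clusters seen in a single library were those with at least 20 counts in it and an estimate of 0 in the other. Correlations were computed across clusters on log2(CPM + 1), with CPM taken on the adjusted library size. Class medians by length used ratios with 0.5 added to each count, with intervals from 1000 bootstrap draws over clusters. Clusters are not independent replicates. Named clusters were the 2 highest-ranked in each direction by the interval bound nearest to equality, plus the 3 most abundant of each library, a rule fixed before the data were examined. A reference for counting error alone was made by drawing Poisson counts with the same mean abundance in both libraries.

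The interval method was tested on simulated counts for the DgWRKY5 against CK comparison over all 153887 clusters, with 200 changed clusters of at least 100 summed counts. Of 50 clusters each, it recovered 50 that were 4-fold higher, 42 that were 4-fold lower, 50 that were 8-fold higher and 49 that were 8-fold lower. It called 4 unchanged clusters. Alternatives comprised other scalings (including the size factors of DESeq2 1.42.0), other count minimums, other fold and interval thresholds, ratios of the deposited FPKM values, counts summed per family and thinning of the deeper library. Leaving out a replicate was not possible with 1 library per group. Figures were drawn with matplotlib 3.10.9.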

Results

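Leaf transcriptomes of chrysanthemum, an ornamental polyploid of the daisy family, were compared between a library titled CK and a library from plants transgenic for DgWRKY5, a gene named for the WRKY family of plant transcription factors. Each group was represented by 1 library, of 15980744 counts for CK and 16486004 counts for DgWRKY5. The values are the authors' estimated counts and FPKM for 153887 assembled transcript clusters. In all, 21530 clusters (14.0%) were at 0 in both libraries. There were no replicates, so the differences below hold between the libraries, and intervals cover counting error only.

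The set of transcripts seen was of similar size in both libraries. At least 1 count was found for 117780 clusters in the CK library and for 116775 in the DgWRKY5 library, of which 102361 were shared. At least 10 counts were found for 64846 clusters in CK and 63170 in DgWRKY5. After the DgWRKY5 library was thinned to the depth of the CK library, it held 116405 clusters with at least 1 count and 62392 with at least 10. An FPKM of at least 1 was reached by 78406 clusters in CK and 74656 in DgWRKY5.

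The most abundant transcripts were largely shared, and they took a larger share of the DgWRKY5 library. The top 10 clusters held 5.98% of the counts in CK (exact 95% interval 5.97 to 5.99%) and 6.28% in DgWRKY5 (6.26 to 6.29%). The top 100 held 19.3% in CK (19.3 to 19.4%) and 21.6% in DgWRKY5 (21.6 to 21.6%), and the top 1000 held 42.1% and 44.6%. The lists of the top 10, 100 and 1000 clusters shared 8, 68 and 725 members. The same 3 clusters led both libraries. Cluster-23284.63597, with an implied length of 914 nt, held 1.05% of the CK counts and 1.29% of the DgWRKY5 counts. Cluster-23284.63975 (1845 nt) held 0.973% and 0.777%, and Cluster-23284.63584 (526 nt) held 0.740% and 0.820%. After TMM scaling, their DgWRKY5 to CK ratios were 1.31 (1.30 to 1.32), 0.854 (0.848 to 0.861) and 1.19 (1.18 to 1.20), all within 2-fold.

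To ask how leaf transcript levels differed between the DgWRKY5 and CK libraries, the ratio of each cluster was compared with 2-fold. Of 63953 measured clusters, which held 98.4% of the CK counts and 98.5% of the DgWRKY5 counts, 3985 (6.23%) were higher in the DgWRKY5 library and 3998 (6.25%) were lower. The other 55970 (87.5%) had an interval that did not lie wholly beyond 2-fold. The higher clusters held 14.6% of the DgWRKY5 counts and 4.17% of the CK counts. The lower clusters held 2.39% of the DgWRKY5 counts and 8.59% of the CK counts. Counts drawn with equal means gave 0 higher and 1 lower cluster, so the observed numbers exceed counting error at this depth. Whether they exceed the variation between plants of a single group could not be tested.

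Across measured clusters, Pearson's r of log2(CPM + 1) between the libraries was 0.890 and Spearman's rho was 0.795. Counting error alone gave 0.992 and 0.966. For the 5638 clusters with at least 1000 summed counts, the interquartile range of the log2 ratio was 0.89, against 0.08 from counting error alone.

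**Figure D1:**
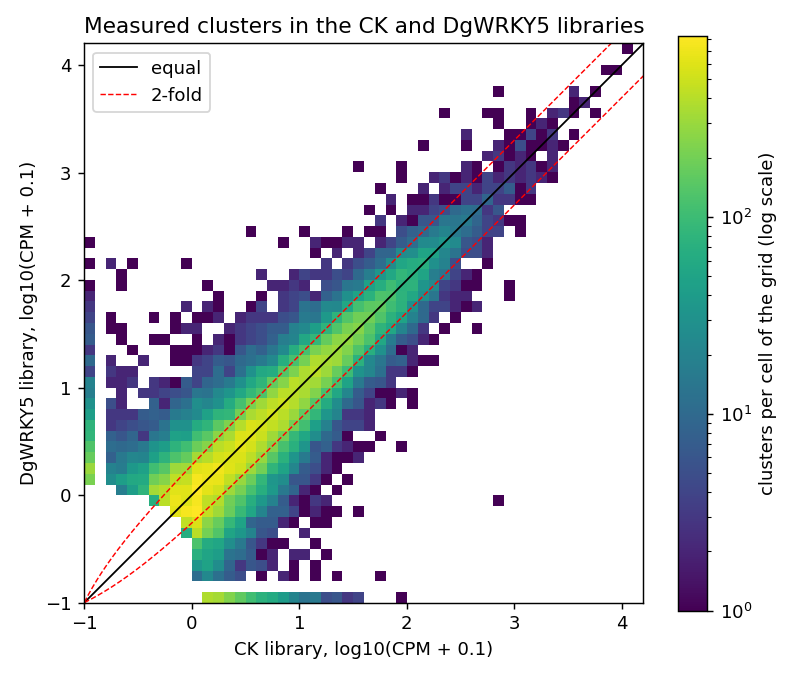
Measured clusters by their level in the CK library (x axis) and the DgWRKY5 library (y axis), both as log10(CPM + 0.1), with colour for the number of clusters per cell of the grid on a log scale. The 63953 clusters are densest along the line of equality, and clusters with 0 counts in a library form separate strips along the left and lower edges.

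The highest-ranked cluster in the DgWRKY5 library was Cluster-23284.51427, with an implied length of 2038 nt. It had 3199 counts (FPKM 95.23) there and 0 in the CK library, and the exact 95% interval of its ratio began at 898-fold higher. Cluster-23284.90599 (1743 nt) followed with an estimate of 2008.5 counts (FPKM 69.91) against 0, with an interval from 564-fold higher. In the other direction, Cluster-23284.64771 (1742 nt) had an estimate of 10837.86 counts in the CK library and 11.62 in the DgWRKY5 library. Its FPKM was 389.34 in CK and 0.40 in DgWRKY5, and it was 871-fold lower in DgWRKY5 (95% interval 499 to 1687). Cluster-23284.43753 (417 nt) had an estimate of 1414.3 counts (FPKM 212.29) in CK and 0 in DgWRKY5, with an interval from 369-fold lower. All of these clusters except Cluster-23284.51427 had a non-whole estimate, so their levels are uncertain. The intervals do not cover how reads were divided between similar sequences, and all 4 clusters lie in the same family. The files name no gene for any of the 4 clusters.

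Differences were found at every level of abundance, and the balance between higher and lower clusters shifted with it. In the lowest quartile of summed counts (20 to 38), 1028 of 15979 clusters were higher in the DgWRKY5 library and 1249 lower. In the highest quartile (276 and above), 1105 of 16007 were higher and 821 lower, a balance that turned with total-count scaling to 955 higher and 1014 lower. Classes by powers of 10 were added after seeing the data. Among clusters with 20 to under 100 summed counts, 2114 of 34449 were higher in the DgWRKY5 library and 2398 were lower. Among those with 100 to under 1000 counts, 1406 of 23866 were higher and 1265 lower. Among those with 1000 to under 10000 counts, 411 of 5325 were higher and 310 lower, and with total-count scaling 360 were higher and 384 lower. Of the 313 clusters with 10000 or more counts, 54 (17.3%) were higher and 25 (7.99%) lower. In that class the higher clusters outnumbered the lower ones under all 3 other scalings as well, with 51 against 27 with DESeq2 size factors, 50 against 32 with total counts and 55 against 23 with the upper quartile. Of the 132 clusters in the top 100 of either library, 31 were higher in the DgWRKY5 library and 11 were lower.

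**Figure D2:**
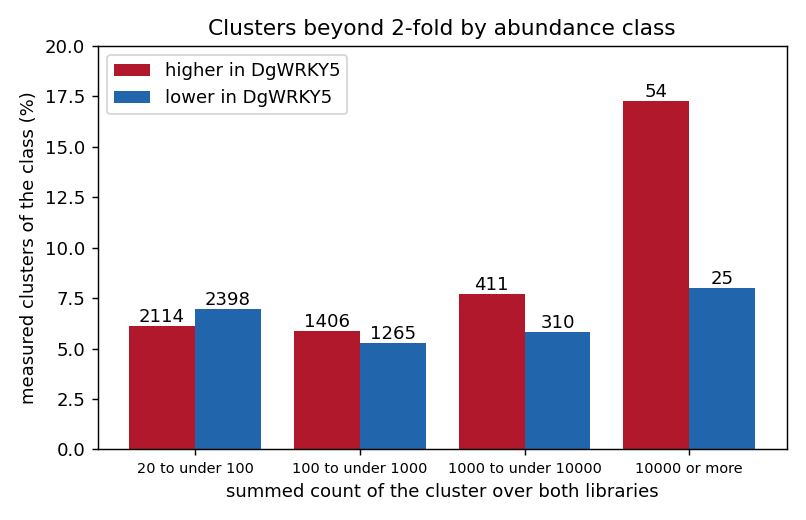
Percentage of measured clusters (y axis) whose whole 95% interval lay above 2-fold (red) or below it in the other direction (blue) in the DgWRKY5 library relative to CK, by summed count (x axis), with the number of clusters above each bar. Higher and lower clusters are close in number below 1000 counts, while 54 against 25 were counted at 10000 or more.

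Among abundant clusters, the ratio also varied with implied length. Over all measured clusters the median log2 ratio was 0.02 in the shortest quartile (774 higher and 824 lower of 15864) and -0.04 in the longest (1204 higher and 1137 lower of 15864), a difference of 0.06 (bootstrap 95% interval 0.03 to 0.10). The split by abundance was added after seeing the data. Clusters with at least 1000 summed counts and an implied length under 509 nt had a median log2 ratio of 0.34, with 61 of 490 higher in the DgWRKY5 library and 13 lower. Those over 1458 nt had a median of -0.06, with 167 of 2497 higher and 159 lower. The difference between the medians was 0.40 (bootstrap 95% interval 0.33 to 0.48). Another scaling shifts all these medians alike, by -0.10 to 0.06, and leaves their difference as it is. The difference was 0.34 (0.21 to 0.43) among clusters with whole-number estimates in both libraries. At 100 to under 1000 counts the difference was 0.12 (0.08 to 0.16), and at 20 to under 100 counts it was -0.01 (-0.05 to 0.03). At 100 to under 1000 counts, 276 clusters were higher and 205 lower in the shortest quartile, and 438 and 454 in the longest. At 20 to under 100 counts the balance was reversed. There, 437 of 11863 were higher and 606 lower in the shortest quartile, and 599 of 5029 were higher and 524 lower in the longest. These numbers include clusters seen in a single library, which are beyond 2-fold by definition and lie mostly in this class. Over all measured clusters, the shortest quartile held 325 seen only in CK and 117 seen only in DgWRKY5. The longest held 341 and 457. Without these, higher clusters outnumbered lower ones in the shortest quartile, and lower outnumbered higher in the longest. The shortest quartile made up 8.69% of clusters at 1000 counts or more, 14.7% at 100 to under 1000 and 34.9% at 20 to under 100.

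**Figure D3:**
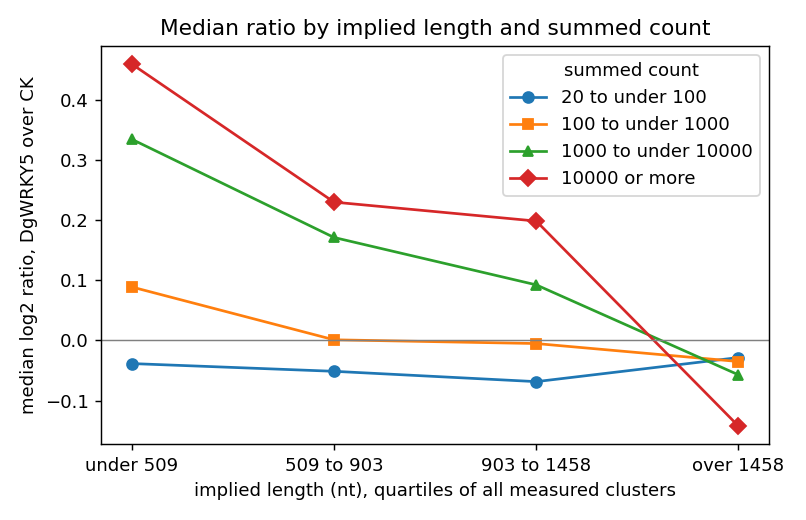
Median log2 ratio of DgWRKY5 over CK (y axis) by quartile of implied length in nt (x axis), with a line for each class of summed count and a grey line at equality. In the class of 1000 to under 10000 counts the median is 0.34 in the shortest quartile and -0.06 in the longest, and in the class of 20 to under 100 counts it lies between -0.07 and -0.03.

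A number of clusters were seen in a single library. The CK library alone held 1432 clusters with at least 20 counts and an estimate of 0 in DgWRKY5, and the DgWRKY5 library alone held 1118, of which 259 lay in the families numbered below 5100. Equal-mean counts gave 0 such clusters for each library. Their share of the reads was 0.441% in CK and 0.440% in DgWRKY5, and their median counts were 32 and 33. At least 100 counts were reached by 113 of the CK clusters and 108 of the DgWRKY5 clusters, and at least 500 counts by 5 and 18. The balance varied with implied length, with 325 CK clusters against 117 DgWRKY5 clusters in the shortest quartile and 341 against 457 in the longest.

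The cluster names divide the transcripts into families, and the numbers of higher and lower clusters differed between them. A single family, numbered 23284, held 117161 clusters, and its measured clusters held 97.5% of all CK counts and 97.6% of all DgWRKY5 counts. It had 3383 higher and 3300 lower clusters among 57692 measured (11.6%). Families of several clusters outside it had 164 higher and 188 lower among 1840 (19.1%), and families of 1 cluster had 438 higher and 510 lower among 4421 (21.4%). Clusters seen in a single library are beyond 2-fold by their definition and are part of these numbers. In the largest family, 884 were seen only in CK and 771 only in DgWRKY5. Families of several had 133 and 97, and families of 1 had 415 and 250. Without them, the shares outside the largest family were not higher than inside it. Outside the largest family, higher and lower clusters were also counted by family number, in blocks set after seeing the data. The limit of 5100 was set on the CK values. Below it nearly all clusters are at 0 in CK, so a measured cluster there is almost bound to be higher in DgWRKY5. Families below 600 had 134 higher and 0 lower clusters among 134 measured, and families 600 to below 5100 had 132 higher and 1 lower among 142. Families from 5100 upward had 336 higher and 697 lower among 5985. The limit shaped this balance too, since it left 259 clusters seen only in DgWRKY5 below 5100. From 5100 upward, 547 clusters were seen only in CK and 88 only in DgWRKY5. Without these, higher clusters outnumbered lower ones there. In families below 600, 98.5% of 668 clusters were at 0 in the CK library and 3.74% in the DgWRKY5 library. In families 600 to below 5100, 98.7% of 5064 clusters were at 0 in CK, 70.9% in DgWRKY5 and 70.5% in both.

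**Figure D4:**
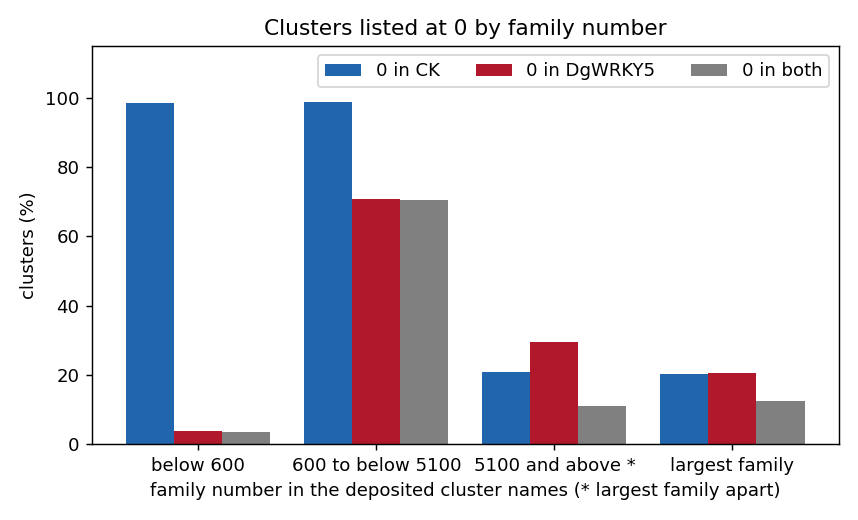
Percentage of clusters (y axis) listed at 0 in the CK library (blue), in the DgWRKY5 library (red) and in both (grey), by family number in the deposited names (x axis), with the largest family shown apart. Families below 600 and 600 to below 5100 are at 0 in CK for 98.5% and 98.7% of clusters, against 20.8% in families from 5100 upward.

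Where several clusters of a small family were beyond 2-fold, they mostly went the same way. To set aside the families below 5100, this was counted in families from 5100 upward. Among 389 of these outside the largest with at least 2 measured clusters, 37 had 2 or more clusters beyond 2-fold. In 33 of these all such clusters went the same way, and in 4 they went both ways. Random reassignment of the directions among these clusters gave a mean of 20.5 families with all the same way (at most 29 in 1000 draws) and 16.5 with both ways (at least 8). The reassignment treats clusters of a family as independent. Clusters seen in a single library are part of these numbers. In such families they numbered 161, and for 117 of them all relatives were at 0 in the other library.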

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

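The subsets by whole-number estimates, by largest family, by family number and by detection in both libraries were chosen after seeing the data. Scaling moved the main counts little. They ranged from 3604 higher and 4540 lower clusters with total counts only to 4273 and 3746 with the upper quartile, with log2 shifts of -0.10 to 0.06, and the 4 named clusters kept their direction. A wider interval (alpha of 0.001) gave 2799 higher and 2714 lower, and thinning gave 3898 and 4018. Thresholds moved the counts by over 1.5 times. With at least 1 summed count there were 6192 higher and 6261 lower clusters, and with at least 100 there were 1871 and 1600. A point ratio beyond 2-fold gave 9305 and 10070, and a whole interval beyond 4-fold gave 1819 and 1812. The deposited FPKM, also taken as a point ratio beyond 2-fold without an interval, gave 7806 and 10772. Lengths implied with the column total as depth differed by a median of 0.22% between the libraries. The FPKM ratios thus carry no TMM adjustment, as with total-count scaling, whose log2 shift was -0.10. Counts summed per family left 6221 units and gave 581 higher and 693 lower. This turns the largest family, with 57692 measured clusters, into a single unit and leaves out the differences within it. Clusters with whole-number estimates gave 1383 higher and 1138 lower among 18965. The largest family alone gave 3383 and 3300, and all clusters without the families below 5100, the largest family included, gave 3719 and 3997. Clusters seen in both libraries gave 2867 higher and 2566 lower. Clusters seen only in CK numbered 3602 at a minimum of 10 counts, 113 at 100 and 582 with whole-number estimates. Those seen only in DgWRKY5 numbered 2823, 108 and 431. Pearson's r was 0.927 with at least 1 summed count, 0.840 with at least 100, 0.795 with a pseudocount of 0.1 and 0.869 on log2(FPKM + 1). Spearman's rho was 0.753 with at least 1 summed count and 0.813 on FPKM. Fewer or more clusters enter under each minimum by construction, and the cause of the other shifts was not tested. No paired analysis was possible because each group has 1 library. For the same reason no replicate could be left out. Counts of 0 limit ratios at this depth to the bounds given.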

Other observations

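All tests in this part were chosen after the results were seen. With 1 library per group, a difference between wild-type and transgenic plants stays open for each pattern and was not tested.

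Clusters seen in a single library numbered 2550. The tables argue against counting error, since equal-mean counts gave 0 of them. Reads divided within a family would leave the missing reads in relatives, but in families of several clusters numbered from 5100 upward, the largest apart, all relatives together held fewer reads in the other library than were missing, beyond counting error, for 128 of 161 such clusters (79.5%, exact 95% interval 72.4 to 85.5%). Division within the family may thus account for at most a minority of these, and the 69 in families of several below 5100 were not tested. Another 2320 lie in the largest family, which was left out of the test, or in families of 1, which have no relatives to compare. For these, reads divided between clusters cannot be told apart from a true difference. Transcripts of another organism also stay open, because no sequences were used here. Of all clusters seen in a single library, 64.9% lie in the largest family, against 91.3% of other measured clusters.

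Family numbers below 5100 are almost always at 0 in the CK library. A candidate explanation is that families were numbered library by library, over more libraries than these 2. Among clusters at 0 in CK, the share also at 0 in DgWRKY5 was 3.65% of 658 in families below 600 and 71.4% of 4997 in families 600 to below 5100. Pooled, 63.6% of those in families below 5100 were also at 0 in DgWRKY5 (exact 95% interval 62.3 to 64.8%), against 52.8% in families from 5100 upward with the largest apart (51.5 to 54.0%). Because the limits were set on the values themselves and the first block goes the other way, this comparison does not decide, and the explanation stays open.

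Among abundant clusters, the median ratio of DgWRKY5 to CK was higher for shorter than for longer ones, although most short ones were not beyond 2-fold. Without the clusters of 10000 or more counts, the difference between the shortest and longest quartile was 0.39 on the log2 scale (bootstrap 95% interval 0.31 to 0.46). The class of 1000 to under 10000 counts keeps 457 of the 490 shortest and 2386 of the 2497 longest clusters. A difference of medians could hardly change when so few are left out, so this comparison does not decide on a part of very abundant clusters. A length-dependent yield, from RNA integrity or fragment selection, might be expected at every abundance. The difference was 0.12 at 100 to under 1000 counts and -0.01 (-0.05 to 0.03) at 20 to under 100 counts. In the latter class, 437 clusters were higher and 606 lower in the shortest quartile, and 599 and 524 in the longest. Clusters seen in a single library lie mostly in that class and are part of these numbers. Over all measured clusters they numbered 325 for CK and 117 for DgWRKY5 in the shortest quartile. In the longest they numbered 341 and 457, so these counts do not decide on yield. A length-dependent yield still cannot be told apart from a difference in which transcripts are abundant. The reason is that short clusters are more frequent at low counts (14.7% against 8.69%) and broken assemblies of long transcripts would hide a trend there.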
